A study of Homo sapiens with 12 samples.

How the data were processed

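RNA was measured in 12 libraries of human umbilical vein endothelial cells, 4 non-treated (NT), 4 transduced with wild-type TIE2 (TIE2-WT) and 4 transduced with TIE2-L914F. Per the labels' protocols, cells were grown in Endothelial Growth Medium, total RNA was isolated with the RNeasy mini kit, and 500 ng were used for strand-specific libraries with the NEBNext Ultra II Directional kit and 9 PCR cycles. How the cells were transduced and selected, and whether the libraries of a group came from separate cultures or donors, is not given in the sources used here. The submitters' processing notes name FastQC 0.12.1, Trim Galore 0.6.10, STAR 2.6.1d and Salmon 1.10.3 and the builds hg38 and mm10, with no role or order. The gene annotation, the strand setting and the handling of reads shared between genes are not given in the sources used here.

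The authors deposited 1 table of TPM, a length-corrected share of transcripts, with 26475 genes, named by symbol alone, in which each library sums to 1000000. Library names in the labels tied each column to its sample. TPM keep neither read counts nor depth, so no count model and no counting interval was used, and the precision rests on the spread between the 4 libraries of a group. Because TPM are shares of a fixed total, a rise of abundant transcripts lowers the values of the others. XIST and Y-linked genes (107) were left out of every step, which left 26368 genes. Of the remaining symbols, 23642 matched a current symbol of the RefSeq annotation of GRCh38.p14, from which gene positions were taken. Older symbols are printed as deposited, with the current one at first mention for some. The mitochondrially encoded list matched 0 rows.

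Differences were tested with limma 3.58.1 in R 4.3.3, two-sided, with a mean-variance trend and empirical Bayes moderation on log2(TPM + 1), for the 12173 genes with a mean of at least 1 TPM over all libraries. All 12 libraries entered 1 fit with 3 groups, which share an estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were TIE2-L914F against TIE2-WT, TIE2-L914F against NT and TIE2-WT against NT, together with the relation between both transduced groups relative to NT and the genes that differed in TIE2-L914F from both other groups. SE values are the moderated standard errors of the log2 difference. For comparisons that share libraries, 100 simulations of unchanged groups, the overlap of independent lists and all 6 splits of the shared libraries are given beside the observed values.

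The design, the gene lists and the rule for named genes were fixed before the data were examined. For each comparison the rule took the 8 largest rises and the 8 largest falls on the log2(TPM + 1) scale among genes past the threshold whose libraries did not overlap between the groups and whose symbol is not a clone, LOC, LINC or antisense identifier. It added TEK and, from each list described, members with the smallest adjusted p in that comparison. Up to 3 were named between TIE2-L914F and TIE2-WT and 2 elsewhere, fewer than the maximum per list that the rule as fixed allowed.

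The 36 lists hold 862 entries, of which 848 matched the table, 50 of them by an older symbol; a gene can stand in more than 1 list. They cover the TIE receptor axis, FOXO targets, coagulation, mural cell ligands, matrix, matrix proteases, arterial, venous, lymphatic and tip cell genes, and endothelial identity. Further lists cover inflammation, interferon response, antigen presentation, proliferation, cholesterol and fatty acid synthesis, glycolysis and hypoxia, ATF4 and unfolded protein responses, MAPK feedback, and mesenchymal, BMP, YAP and TAZ, and KLF2 genes. The rest are p53 targets, senescence, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, histones, immediate early genes, and markers of smooth muscle and fibroblasts, leukocytes, erythroid cells and platelets, and epithelium and amnion. Each of the 34 lists with at least 5 tested members was tested with limma's camera with a preset correlation of 0.01 and again with a correlation estimated per list, adjusted over lists within a comparison.

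Alternatives chosen beforehand were a pseudocount of 0.1, a minimum mean of 5 TPM, no filter, median-of-ratios rescaling (factors between 0.965 and 1.037), TEK left out of the total, limma without trend, sample quality weights, a fit of only the groups compared, the replicate number as a block, each library left out in turn and an added 2-fold threshold. Leaving out ribosomal RNA and leaving out the libraries numbered 4 were added after the data were seen. The procedure was tested on simulated data for TIE2-L914F against TIE2-WT with 12173 genes, 50 of them changed at each size. It recovered 76% of changes of 0.25, 96% of 0.5, 100% of 1 and 100% of 2 on the log2 scale, with 7 false among 193 calls. The changes were placed only in more abundant genes, so recovery for genes with low TPM was not tested. Few genes were changed and the simulated values were not brought to a fixed total. False calls from shifted shares, where many genes change, were therefore not tested. Of 50 simulated lists, the 1 that was shifted was called and 0 of the others were. The simulated genes were independent, so false calls among lists of correlated genes were not tested.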

Results

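Gene expression was measured by RNA sequencing in human umbilical vein endothelial cells (HUVEC), primary cells from the inner lining of the umbilical vein. The 12 libraries fall into 3 groups of 4: non-treated cells (NT), cells transduced with wild-type TIE2 (TIE2-WT) and cells transduced with the mutant form TIE2-L914F. TIE2 is an endothelial receptor tyrosine kinase that binds angiopoietins and is encoded by TEK. The L914F substitution lies in its kinase domain and is known from sporadic venous malformations. No label says that the libraries of a group came from separate cultures or donors, so the p-values measure only the spread between these libraries, which may be technical. The deposited values are TPM, which keep no depth. The depth per library is therefore unknown, and no counting interval is given.

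Of the 26368 genes considered, 12173 had a mean of at least 1 TPM and were tested. The libraries separated by group: the leading principal component held 67.4% of the variance and the next 11.9%, and each of the 12 libraries correlated best with a library of its own group. Across genes, the correlation of log2(TPM + 1) was between 0.994 and 0.997 within groups and at most 0.990 between groups. Ribosomal RNA made up 3.11% ± 0.391 of the TPM in NT, 3.24% ± 0.657 in TIE2-WT and 2.74% ± 0.246 in TIE2-L914F (SD, n = 4), with overlapping ranges. In each group its share was highest in the library numbered 4. Fold changes below are differences of mean log2(TPM + 1), which understate the change of genes with low TPM.

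TEK was measured in every library first, because it encodes the introduced receptor. TEK lies on chromosome 9 (27109225 to 27230174, GRCh38.p14). Its level was 61.8 ± 2.20 TPM in NT, 8761 ± 328 TPM in TIE2-WT and 6191 ± 287 TPM in TIE2-L914F (SD, n = 4). The log2 difference from NT was 7.12 in TIE2-WT (SE 0.03, limma adjusted p = 1.67e-22) and 6.62 in TIE2-L914F (SE 0.03, adjusted p = 4.84e-22). TIE2-L914F held less TEK transcript than TIE2-WT, by a log2 difference of -0.50 (SE 0.03, adjusted p = 9.58e-09). TEK made up 0.85% to 0.92% of the TPM in the TIE2-WT libraries and 0.58% to 0.65% in the TIE2-L914F libraries. The TPM of this gene does not separate transcripts of the introduced construct from those of the cells' own gene.

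**Figure D1:**
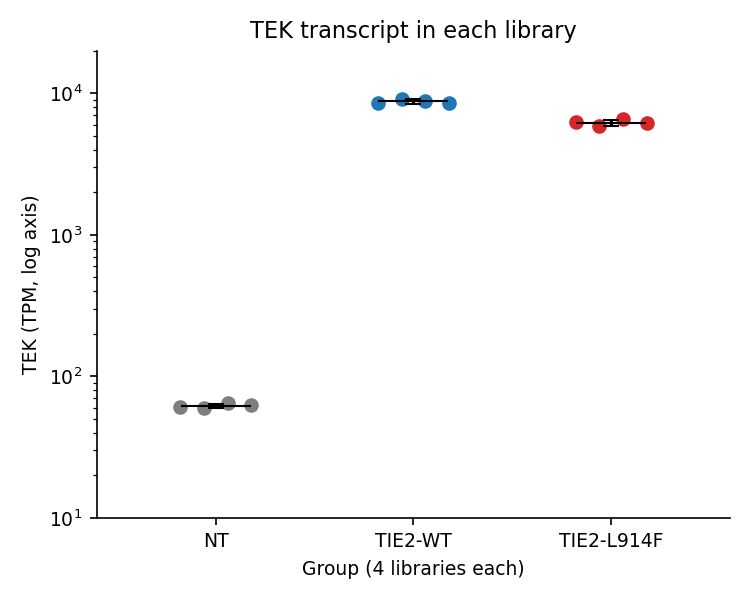
TEK transcript in each library in TPM on a log axis, by group; points are libraries, bars mark the mean and whiskers the SD (n = 4). The TIE2-WT libraries lay around 8761 TPM and the TIE2-L914F libraries around 6191 TPM, far above the NT libraries around 61.8 TPM.

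The comparison of TIE2-L914F with TIE2-WT asks what changes when the mutant in place of the wild-type receptor is introduced. Of the interferon response genes, 31 of 34 tested rose and 0 fell, with a median log2 change of 0.97 (camera adjusted p = 2.17e-18; adjusted p = 0.0264 with an estimated correlation). The insulin-like growth factor binding protein gene IGFBP5 went from 2.09 ± 0.241 TPM in TIE2-WT to 73.5 ± 5.11 TPM in TIE2-L914F, and the matrix protease gene ADAMTS5 from 0.369 ± 0.0659 to 26.6 ± 1.48 TPM (SD, n = 4). EDN1, which encodes the vasoconstrictor endothelin, went the other way, from 136 ± 10.1 to 7.14 ± 1.09 TPM, as did the elastic fibre gene FBLN5, from 21.9 ± 1.03 to 0.0846 ± 0.0859 TPM. Of the 12173 genes tested, 3116 rose and 3706 fell, of which 175 and 225 changed by at least 2-fold.

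Among the largest rises were IGFBP5 (log2 change 4.59, SE 0.07, limma adjusted p = 8.05e-16), ADAMTS5 (4.33, SE 0.07, adjusted p = 1.35e-15) and ADAMTS1, a further matrix protease gene (2.53, SE 0.05, adjusted p = 5.64e-15). The neuropeptide gene NTS rose by 2.72, the apelin receptor gene APLNR by 2.66, the TGF-beta family ligand gene GDF3 by 2.53, the fatty acid carrier gene FABP3 by 2.41 and the stanniocalcin gene STC1 by 2.40 on the log2 scale. Among the largest falls were FBLN5 (-4.40, SE 0.09, adjusted p = 1.09e-14), the FOXO-induced gene C10orf10 (now DEPP1; -4.29, SE 0.07, adjusted p = 8.05e-16) and EDN1 (-4.08, SE 0.08, adjusted p = 5.52e-15). They were followed by the chemokine gene CCL14 (-4.05), the bone morphogenetic protein gene BMP4 (-3.44), the chemokine receptor gene CXCR4 (-2.999), the platelet-derived growth factor gene PDGFB (-2.83) and the acid phosphatase gene ACP5 (-2.71). CXCR4 was at 7.43 ± 0.60 TPM in TIE2-WT and 0.0538 ± 0.0634 TPM in TIE2-L914F. IGFBP5 lies on chromosome 2 (216672105 to 216695549), ADAMTS5 and ADAMTS1 on chromosome 21 (26917922 to 26967088 and 26835755 to 26845409), FBLN5 on chromosome 14 (91869411 to 91947694) and EDN1 on chromosome 6 (12230516 to 12297194). CCL14 overlaps a readthrough transcript of its neighbouring chemokine gene, so its value is uncertain.

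**Figure D2:**
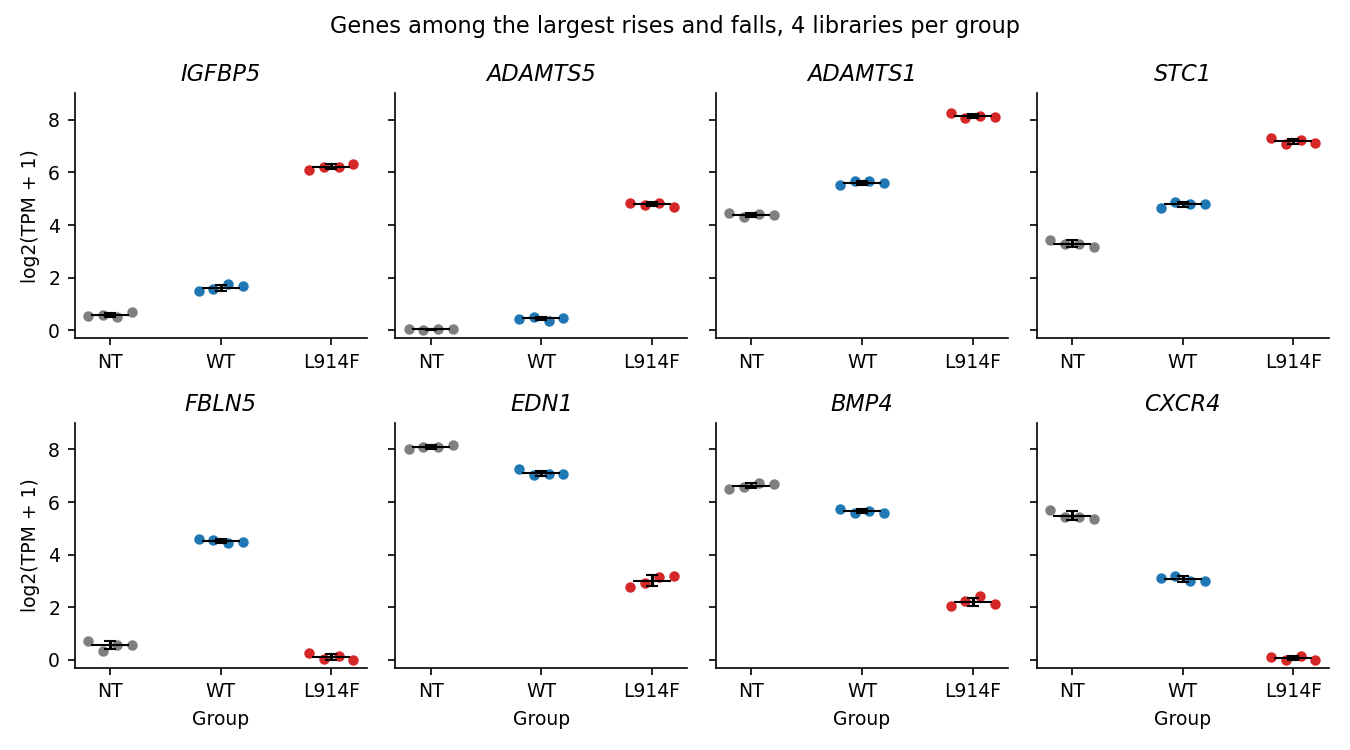
Expression of 8 genes in each library as log2(TPM + 1), by group (WT, TIE2-WT; L914F, TIE2-L914F); points are libraries, bars mark the mean and whiskers the SD (n = 4). IGFBP5, ADAMTS5, ADAMTS1 and STC1 were highest in TIE2-L914F, EDN1, BMP4 and CXCR4 were lowest there, and FBLN5 was high in TIE2-WT alone (21.9 TPM).

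Gene groups fixed before the data were examined were counted member by member and tested with camera. Among the interferon response genes, IFI6 rose by 2.08, the RNA sensor gene OAS2 by 2.38 and the antiviral GTPase gene MX1 by 2.09 on the log2 scale. Among antigen presentation genes, 13 of 15 rose and 1 fell (median 0.68, camera adjusted p = 1.55e-08; adjusted p = 0.0195 with an estimated correlation). The immunoproteasome subunit gene PSMB9 went from 11.99 ± 0.381 to 47.4 ± 2.96 TPM, and the peptide transporter gene TAP1 rose by 1.29 and HLA-C by 0.98 on the log2 scale. Inflammatory adhesion and NF-kB genes rose in 15 of 19 cases and fell in 1 (median 0.51, camera adjusted p = 7.00e-05; adjusted p = 0.0196 with an estimated correlation). The chemokine gene CCL2 went from 17.6 ± 1.04 to 67.4 ± 2.86 TPM and the NF-kB inhibitor gene NFKBIA rose by 0.84 on the log2 scale, while the pentraxin gene PTX3 fell (-0.93).

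Leukocyte markers moved with these 3 groups: 4 of 5 tested rose and 0 fell (median 0.51, camera adjusted p = 0.00700; adjusted p = 0.0580 with an estimated correlation). They were led by LAPTM5 (log2 change 1.12), CD14 (1.53) and CD68 (0.32), genes of lysosomal and lipopolysaccharide-binding proteins. The pan-leukocyte marker PTPRC was listed at 0 in the TIE2-L914F libraries and the B cell marker CD79A stood at 0.146 ± 0.108 TPM.

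Of the cholesterol synthesis genes, 24 of 25 rose and 0 fell (median 0.64, camera adjusted p = 2.61e-15), although not past the threshold with a correlation estimated from the data (adjusted p = 0.0580 with an estimated correlation). The sterol sensor gene INSIG1 went from 143 ± 2.90 to 325 ± 11.1 TPM, and HMGCS1 rose by 1.18 and EBP by 0.91 on the log2 scale. Among fatty acid synthesis genes, 12 of 14 rose and 1 fell (median 0.67, camera adjusted p = 2.00e-07; adjusted p = 0.0527 with an estimated correlation). Members included the desaturase genes FADS2 (1.13) and SCD (0.77) and the malic enzyme gene ME1 (1.03). Glycolysis and hypoxia genes rose in 19 of 28 cases and fell in 8 (median 0.28, camera adjusted p = 2.79e-04; adjusted p = 0.134 with an estimated correlation). PKM rose by 0.49, NDRG1 by 0.82 and the glucose transporter gene SLC2A3 by 0.68. For oxidative phosphorylation genes 14 of 32 rose and 1 fell (median 0.07, camera adjusted p = 0.00185; adjusted p = 0.1196 with an estimated correlation), by 0.40 for ATP5G3, 0.37 for ATP5G1 and 0.31 for CYC1.

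Amino acid response ATF4 genes rose in 19 of 29 cases and fell in 5 (median 0.19, camera adjusted p = 2.02e-04; adjusted p = 0.0580 with an estimated correlation). Their leading members were the mTOR inhibitor gene DDIT4 (1.38), the pseudokinase gene TRIB3 (1.08) and ATF3 (1.13). Of the unfolded protein response genes, 17 of 22 rose and 2 fell (median 0.32, camera adjusted p = 3.46e-07; adjusted p = 0.0811 with an estimated correlation). Members included the chaperone genes CALR (0.58), PDIA4 (0.55) and PDIA6 (0.41). Immediate early and heat stress genes rose in 10 of 14 cases and fell in 3 (median 0.34, camera adjusted p = 0.00262; adjusted p = 0.0950 with an estimated correlation). HSPA1B rose by 0.93 on the log2 scale and JUN fell (-0.58). Of the KLF2 and flow genes, 9 of 13 rose and 3 fell (median 0.76, camera adjusted p = 0.00742; adjusted p = 0.0580 with an estimated correlation). The lipid phosphatase gene PPAP2B (now PLPP3) rose by 1.20 on the log2 scale, whereas CTGF, a matricellular protein gene (-2.58), and the caveolin gene CAV1 (-0.77) fell. Matrix proteases and inhibitors rose in 13 of 21 cases and fell in 6 (median 0.43, camera adjusted p = 0.00503; adjusted p = 0.118 with an estimated correlation), ADAMTS5 and ADAMTS1 upward and the collagenase gene MMP1 downward (-1.16).

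FOXO target genes fell: 20 of 28 were lower in TIE2-L914F and 3 higher (median -0.54, camera adjusted p = 1.96e-05; adjusted p = 0.0580 with an estimated correlation). The angiopoietin gene ANGPT2, a ligand of TIE2, went from 15.6 ± 1.15 to 3.45 ± 0.160 TPM, and CITED2 (-1.77) and YPEL3 (-1.17) fell. Of the YAP and TAZ genes, 13 of 21 fell and 4 rose (median -0.45, camera adjusted p = 3.81e-04; adjusted p = 0.127 with an estimated correlation). The matricellular protein genes CTGF (now CCN2) and CYR61 (now CCN1) went from 422 ± 19.4 to 69.8 ± 4.04 TPM and from 281 ± 8.46 to 54.1 ± 4.53 TPM, and ANKRD1 fell (-1.66). Matrix and basement membrane genes fell in 17 of 25 cases and rose in 7 (median -0.32, camera adjusted p = 0.00388; adjusted p = 0.260 with an estimated correlation). Members included THBS1 (-2.66), BGN (-2.16) and FBLN5. Endothelial to mesenchymal and TGF-beta genes fell in 14 of 22 cases and rose in 6 (median -0.24, camera adjusted p = 0.0179; adjusted p = 0.220 with an estimated correlation). CTGF (-2.58) and the cadherin gene CDH2 (-1.12) fell. Smooth muscle and fibroblast markers moved the same way: 6 of 7 tested fell and 1 rose (median -0.46, camera adjusted p = 0.0251; adjusted p = 0.0922 with an estimated correlation). Members included PDGFRL (-1.18), TWIST2 (-0.49) and FAP (-0.46).

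Of the BMP and SMAD1/5 genes, 9 of 15 fell and 2 rose (median -0.23, camera adjusted p = 0.0118; adjusted p = 0.0841 with an estimated correlation). The ligand genes BMP4 (-3.44), BMP2 (-1.34) and BMP6 (-1.17) fell. MAPK feedback genes fell in 17 of 23 cases and rose in 6 (median -0.28, camera adjusted p = 0.00262; adjusted p = 0.118 with an estimated correlation). IER3 changed by -1.06 and HMGA1 by -0.78, while the urokinase receptor gene PLAUR rose by 0.81. Arterial and Notch genes fell in 12 of 22 cases and rose in 7 (median -0.30, camera adjusted p = 0.0366; adjusted p = 0.272 with an estimated correlation). C10orf10, FBLN5 and CXCR4 were among those that fell. Lymphatic endothelial genes fell in 7 of 9 cases and rose in 1 (median -0.43, camera adjusted p = 0.00262; adjusted p = 0.0580 with an estimated correlation). Members included the transcription factor gene SOX18 (-1.79), the hyaluronan receptor gene LYVE1 (-1.16) and MMRN1 (-0.73). Cytosolic ribosomal protein genes fell in 37 of 54 cases and rose in 2, by small amounts (median -0.10, camera adjusted p = 3.68e-06; adjusted p = 0.236 with an estimated correlation); RPL3 was at -0.30, RPL5 at -0.23 and RPL23 at -0.23.

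The remaining lists were not called between TIE2-L914F and TIE2-WT. Proliferation genes rose in 10 and fell in 16 of 40 cases (camera adjusted p = 0.575), endothelial identity genes rose in 10 and fell in 8 of 26 (0.476), and blood coagulation and fibrinolysis genes rose in 11 and fell in 8 of 23 (0.311). The TIE receptor axis rose in 3 and fell in 3 of 8 members (0.676), endothelial ligands for mural cells in 5 and 7 of 13 (0.676), venous genes in 4 and 2 of 9 (0.0930), and tip cell and angiogenesis genes in 6 and 10 of 17 (0.118). p53 target genes rose in 7 and fell in 13 of 24 cases (0.441), senescence secretome and cell cycle inhibitor genes in 8 and 8 of 17 (0.676), replication-dependent histone genes in 1 and 1 of 11 (0.440), and epithelial and amnion markers in 1 and 4 of 6 (0.109). Erythroid and platelet markers had 0 members past the filter, and 0 mitochondrially encoded genes matched a row of the table, so neither list was tested.

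In all, 23 of 34 lists were called with the preset correlation, 13 upward and 10 downward, and 3 with an estimated correlation. For the TIE receptor axis the median, mean and direction of the test differed in sign. For endothelial identity genes the mean rounded to 0, so its sign could not be compared. Counts adjusted over the list alone were the same as those over all genes, with these exceptions: TIE receptor axis 4 up, proliferation 17 down, ATF4 genes 20 up, unfolded protein response 18 up, BMP and SMAD1/5 genes 10 down, ribosomal proteins 40 down and histone genes 0 down. The arterial and Notch call was lost when the libraries numbered 4 were left out (camera adjusted p = 0.0578), although the median was -0.315 against -0.305 with them. With median-of-ratios rescaling the split of called genes was 3585 up and 3364 down, 51.6% up against 45.7% as deposited, and the count changed by at least 2-fold was 601 with a pseudocount of 0.1 and 261 with a minimum mean of 5 TPM, against 400. HSPA1B, HLA-C and the ribosomal protein genes have near-identical copies that can share their reads, so their values are uncertain.

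**Figure D3:**
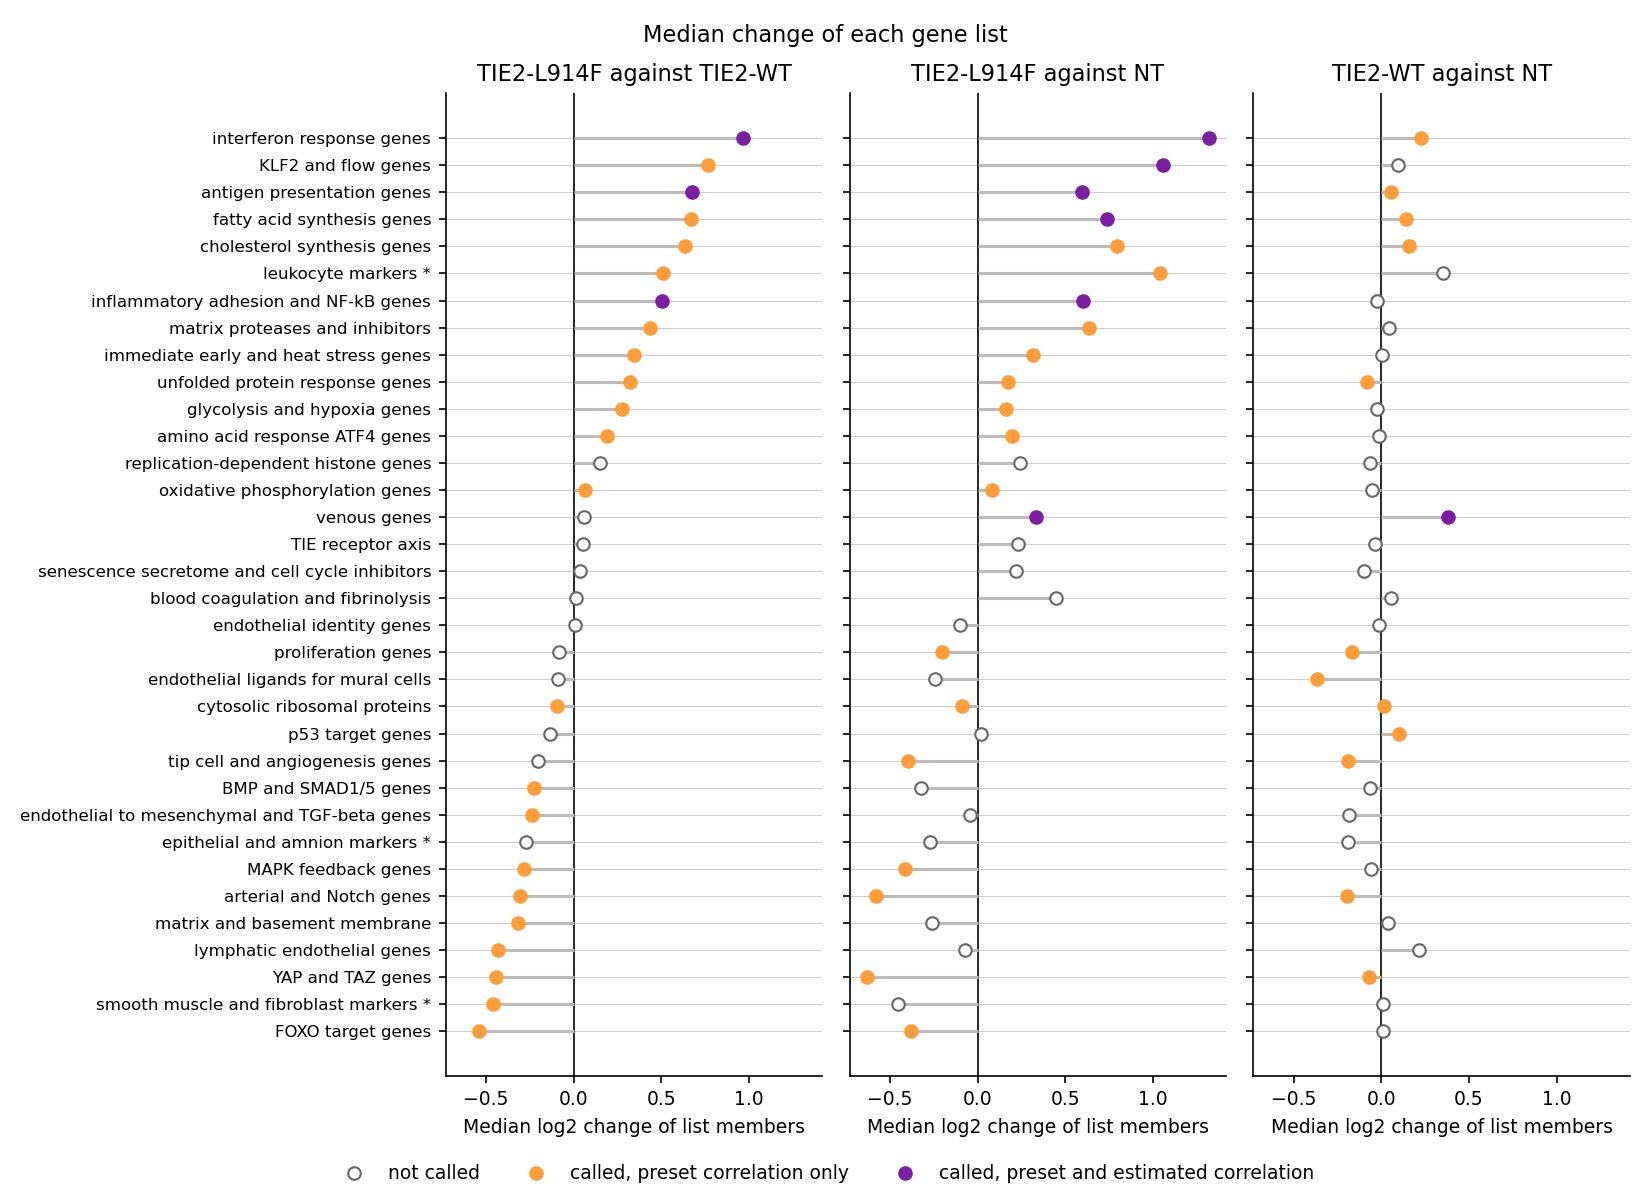
Median log2 change of the tested members of each of the 34 lists in the 3 comparisons; filled points mark lists called by camera at an adjusted p below 0.05 with the preset correlation (orange) or with both the preset and the estimated correlation (purple), and * marks markers of other cell types. Interferon response genes had the highest median in both TIE2-L914F comparisons (0.97 and 1.32).

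Comparing TIE2-L914F with NT shows the mutant receptor against cells that received no construct. Of the interferon response genes, 30 of 34 rose and 0 fell (median 1.32, camera adjusted p = 1.02e-19; adjusted p = 0.0159 with an estimated correlation). OAS1 rose by 2.38 and OAS2 by 3.67. IGFBP5 went from 0.504 ± 0.0837 TPM in NT to 73.5 ± 5.11 TPM in TIE2-L914F, STC1 from 8.86 ± 0.808 to 145 ± 10 TPM and SCUBE1, which encodes a secreted EGF-domain protein, from 3.23 ± 0.427 to 68.2 ± 2.95 TPM (SD, n = 4). C10orf10 went from 385 ± 42.3 to 8.89 ± 0.759 TPM, EDN1 from 272 ± 12.7 to 7.14 ± 1.09 TPM and ANGPT2 from 52.0 ± 3.88 to 3.45 ± 0.160 TPM. Of 12173 genes, 2946 rose and 4469 fell; 326 and 362 of these changed by at least 2-fold.

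After TEK, the largest rises on the log2 scale were IGFBP5 (5.63, SE 0.07, limma adjusted p = 2.16e-17), ADAMTS5 (4.75), SCUBE1 (4.04), STC1 (3.89), ADAMTS1 (3.76), OAS2 (3.67) and GDF3 (3.62). The largest falls were CCL14 (-5.88, SE 0.24, adjusted p = 1.07e-11), CXCR4 (-5.41), C10orf10 (-5.29), EDN1 (-5.08), the fatty acid binding protein gene FABP4 (-4.64), BMP4 (-4.40), PDGFB (-4.35) and the activin antagonist gene FST (-3.94). CXCR4 was at 44.0 ± 5.02 TPM in NT and 0.0538 ± 0.0634 TPM in TIE2-L914F.

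Antigen presentation genes rose in 13 of 15 cases and fell in 1 (median 0.60, camera adjusted p = 4.81e-09; adjusted p = 0.0158 with an estimated correlation). PSMB9 rose by 2.62 and TAP1 by 1.44. Inflammatory adhesion and NF-kB genes rose in 13 of 19 cases and fell in 2 (median 0.60, camera adjusted p = 6.78e-05; adjusted p = 0.0159 with an estimated correlation). CCL2 rose by 2.50, whereas PTX3 fell (-1.18). Leukocyte markers moved with these groups, 3 of 5 up and 1 down (median 1.04, camera adjusted p = 0.0124; adjusted p = 0.0845 with an estimated correlation); LAPTM5 rose by 1.47 and CD68 by 1.04 while PTPRC was listed at 0. Venous genes rose in 7 of 9 cases and fell in 1 (median 0.34, camera adjusted p = 1.64e-04; adjusted p = 0.0159 with an estimated correlation). APLNR rose by 3.58 and the fenestral diaphragm gene PLVAP by 2.14. KLF2 and flow genes rose in 9 of 13 cases and fell in 4 (median 1.06, camera adjusted p = 0.00286; adjusted p = 0.0423 with an estimated correlation). PPAP2B rose by 1.96, while CTGF fell (-3.64).

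Cholesterol synthesis genes rose in 25 of 25 cases (median 0.79, camera adjusted p = 6.34e-17; adjusted p = 0.0631 with an estimated correlation). HMGCS1 rose by 1.75 and INSIG1 by 1.52. Of the fatty acid synthesis genes, 12 of 14 rose and 1 fell (median 0.74, camera adjusted p = 3.21e-08; adjusted p = 0.0310 with an estimated correlation). Members included FADS2 (1.38) and ME1 (1.41). Glycolysis and hypoxia genes rose in 17 of 28 cases and fell in 8 (median 0.16, camera adjusted p = 0.00418; adjusted p = 0.269 with an estimated correlation). NDRG1 rose by 1.63 and SLC2A3 by 0.88. Oxidative phosphorylation genes rose in 16 of 32 cases and fell in 2 (median 0.08, camera adjusted p = 0.00378; adjusted p = 0.170 with an estimated correlation). CYC1 rose by 0.24 and ATP5B (now ATP5F1B) by 0.16. ATF4 genes rose in 18 of 29 cases and fell in 7 (median 0.20, camera adjusted p = 0.00113; adjusted p = 0.0836 with an estimated correlation). DDIT4 rose by 2.13 and TRIB3 by 1.19. For unfolded protein response genes 14 of 22 rose and 3 fell (median 0.18, camera adjusted p = 9.77e-04; adjusted p = 0.208 with an estimated correlation). Members included CALR (0.57) and PDIA4 (0.42). Immediate early and heat stress genes rose in 9 of 14 cases and fell in 4 (median 0.32, camera adjusted p = 0.00744; adjusted p = 0.155 with an estimated correlation). ATF3 rose by 1.39 and HSPA1B by 1.02. Matrix proteases and inhibitors rose in 13 of 21 cases and fell in 6 (median 0.64, camera adjusted p = 0.00212; adjusted p = 0.107 with an estimated correlation). ADAMTS1 rose (3.76) and MMP1 fell (-1.71).

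FOXO target genes fell in 20 of 28 cases and rose in 6 (median -0.38, camera adjusted p = 0.00113; adjusted p = 0.107 with an estimated correlation). ANGPT2 changed by -3.57 and CITED2 by -2.51. Proliferation genes fell in 26 of 40 cases and rose in 2 (median -0.20, camera adjusted p = 0.00286; adjusted p = 0.377 with an estimated correlation). Members included the ribonucleotide reductase gene RRM2 at -0.62 and the replication helicase gene MCM5 at -0.38. Of the YAP and TAZ genes, 14 of 21 fell and 3 rose (median -0.63, camera adjusted p = 9.77e-04; adjusted p = 0.170 with an estimated correlation); CTGF fell (-3.64) while the ecto-nucleotidase gene NT5E rose by 1.59. MAPK feedback genes fell in 16 of 23 cases and rose in 5 (median -0.41, camera adjusted p = 0.00375; adjusted p = 0.155 with an estimated correlation). IER3 changed by -1.77 and HMGA1 by -0.81. Arterial and Notch genes fell in 14 of 22 cases and rose in 6 (median -0.58, camera adjusted p = 0.0290; adjusted p = 0.289 with an estimated correlation), with falls of C10orf10 and CXCR4. Tip cell and angiogenesis genes fell in 12 of 17 cases and rose in 5 (median -0.40, camera adjusted p = 0.0340; adjusted p = 0.289 with an estimated correlation). Members included the placental growth factor gene PGF at -2.43 and CXCR4 at -5.41. Cytosolic ribosomal protein genes fell in 36 of 54 cases and rose in 2 (median -0.09, camera adjusted p = 0.00212; adjusted p = 0.381 with an estimated correlation). RPL3 changed by -0.27 and RPL13A by -0.25. Their call was lost after median-of-ratios rescaling (median -0.03, camera adjusted p = 0.201).

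Lists not called against NT were the TIE receptor axis (5 up and 3 down of 8, camera adjusted p = 0.0641), blood coagulation and fibrinolysis (14 and 9 of 23, 0.0636), endothelial ligands for mural cells (4 and 7 of 13, 0.248) and matrix and basement membrane (8 and 14 of 25, 0.128). Lymphatic endothelial genes (3 and 4 of 9, 0.379), endothelial identity genes (12 and 14 of 26, 0.691), endothelial to mesenchymal and TGF-beta genes (7 and 10 of 22, 0.1002), BMP and SMAD1/5 genes (3 and 8 of 15, 0.107) and p53 target genes (10 and 7 of 24, 0.249) were not called either. Senescence genes (8 and 7 of 17, 0.464), histone genes (2 and 1 of 11, 0.318), smooth muscle and fibroblast markers (2 and 5 of 7, 0.231) and epithelial and amnion markers (1 and 4 of 6, 0.248) complete them. In all, 21 of 34 lists were called with the preset correlation, 14 upward and 7 downward, and 6 with an estimated correlation; for endothelial identity genes the median, mean and direction of the test differed in sign. Counts adjusted over the list alone differed from those over all genes for lymphatic genes (4 up), the unfolded protein response (4 down), ribosomal proteins (38 down) and histone genes (1 up). With median-of-ratios rescaling the split of called genes was 3700 up and 3592 down, 50.7% up against 39.7% as deposited.

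Setting TIE2-WT against NT shows what the wild-type receptor and its introduction change together. Venous genes rose in 9 of 9 cases (median 0.38, camera adjusted p = 1.19e-08; adjusted p = 0.00417 with an estimated correlation). Members included PLVAP (1.18) and the sialomucin gene EMCN (0.43). FBLN5 went from 0.479 ± 0.156 TPM in NT to 21.9 ± 1.03 TPM in TIE2-WT, SCUBE1 from 3.23 ± 0.427 to 24.8 ± 0.547 TPM and ACP5 from 16.3 ± 1.37 to 82.9 ± 2.65 TPM (SD, n = 4). CXCR4 went from 44.0 ± 5.02 to 7.43 ± 0.60 TPM and the coagulation inhibitor gene TFPI2 from 242 ± 9.85 to 67.7 ± 1.05 TPM. Of 12173 genes, 1783 rose and 2714 fell, of which 53 and 46 changed by at least 2-fold.

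Among the largest rises after TEK were FBLN5 (log2 change 3.96, SE 0.09, limma adjusted p = 1.70e-13), SCUBE1 (2.61), ACP5 (2.28), the kinesin gene KIF19 (2.26), the atypical chemokine receptor gene ACKR3 (2.15) and the protease gene ADAMTS18 (2.15). The pseudogene A2MP1 was at 3.20 ± 0.564 TPM in TIE2-WT and listed at 0 in the other libraries; it can share reads with A2M, so its value is uncertain. Among the largest falls were CXCR4 (-2.41, SE 0.08, adjusted p = 1.19e-11), FABP4 (-2.08), the cystatin gene CST1 (-2.003), the receptor kinase gene KIT (-1.98), CCL14 (-1.83), TFPI2 (-1.82), the cadherin gene CDH6 (-1.82) and the sulfotransferase gene CHST1 (-1.81).

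Interferon response genes rose in 21 of 34 cases and fell in 0 (median 0.23, camera adjusted p = 1.19e-08; adjusted p = 0.169 with an estimated correlation). Members included OAS1 (1.07) and OAS2 (1.30). Of the antigen presentation genes, 5 of 15 rose and 2 fell (median 0.06, camera adjusted p = 0.0454; adjusted p = 0.30 with an estimated correlation). PSMB9 rose by 0.73 and ERAP2 by 0.18. Cholesterol synthesis genes rose in 14 of 25 cases and fell in 2 (median 0.16, camera adjusted p = 3.93e-05; adjusted p = 0.392 with an estimated correlation). HMGCS1 rose by 0.58 and INSIG1 by 0.34. Of the fatty acid synthesis genes, 8 of 14 rose and 1 fell (median 0.14, camera adjusted p = 0.00149; adjusted p = 0.287 with an estimated correlation); ME1 rose by 0.38, while FABP4, which carries fatty acids, was the member that fell. p53 target genes rose in 11 of 24 cases and fell in 3 (median 0.10, camera adjusted p = 0.00180; adjusted p = 0.0834 with an estimated correlation). BTG2 rose by 0.33 and FDXR by 0.41. Cytosolic ribosomal protein genes rose in 15 of 54 cases and fell in 5 (median 0.02, camera adjusted p = 0.0429; adjusted p = 0.666 with an estimated correlation). RPL23 rose by 0.14 and RPS18 by 0.11.

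Proliferation genes fell in 27 of 40 cases and rose in 1 (median -0.17, camera adjusted p = 5.73e-06; adjusted p = 0.392 with an estimated correlation). RRM2 changed by -0.31 and the survivin gene BIRC5 by -0.34. Of the endothelial ligands for mural cells, 9 of 13 fell and 2 rose (median -0.37, camera adjusted p = 0.00333; adjusted p = 0.0834 with an estimated correlation). PDGFB changed by -1.52 and EDN1 by -0.998. Tip cell and angiogenesis genes fell in 9 of 17 cases and rose in 3 (median -0.19, camera adjusted p = 0.00180; adjusted p = 0.287 with an estimated correlation). Members included PGF (-1.08) and CXCR4 (-2.41). Arterial and Notch genes fell in 12 of 22 cases and rose in 5 (median -0.20, camera adjusted p = 0.0454; adjusted p = 0.400 with an estimated correlation). CXCR4 fell (-2.41) and FBLN5 rose (3.96). Unfolded protein response genes fell in 11 of 22 cases and rose in 2 (median -0.08, camera adjusted p = 0.00650; adjusted p = 0.400 with an estimated correlation). Members included HYOU1 (-0.34) and EDEM1 (-0.36). YAP and TAZ genes fell in 10 of 21 cases and rose in 3 (median -0.07, camera adjusted p = 0.0441; adjusted p = 0.433 with an estimated correlation). CTGF changed by -1.06, while NT5E rose by 1.02.

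Among the lists not called, FOXO target genes rose in 11 and fell in 10 of 28 cases (camera adjusted p = 0.958), the TIE receptor axis in 3 and 3 of 8 (0.503), coagulation genes in 10 and 9 of 23 (0.623) and endothelial identity genes in 10 and 11 of 26 (0.839). Matrix genes rose in 11 and fell in 6 of 25 (0.273), matrix proteases and inhibitors in 10 and 5 of 21 (0.0576), lymphatic genes in 5 and 2 of 9 (0.234) and inflammatory adhesion and NF-kB genes in 8 and 5 of 19 (0.422). Glycolysis and hypoxia genes rose in 5 and fell in 10 of 28 (0.324), ATF4 genes in 10 and 9 of 29 (0.503), MAPK feedback genes in 4 and 10 of 23 (0.0576) and oxidative phosphorylation genes in 2 and 9 of 32 (0.479). Endothelial to mesenchymal genes rose in 6 and fell in 11 of 22 (0.106), BMP and SMAD1/5 genes in 5 and 6 of 15 (0.839), KLF2 and flow genes in 5 and 3 of 13 (0.127), senescence genes in 7 and 6 of 17 (0.958) and histone genes in 0 and 0 of 11 (0.775). Immediate early genes rose in 4 and fell in 2 of 14 (0.505), smooth muscle and fibroblast markers in 2 and 2 of 7 (0.567), leukocyte markers in 2 and 1 of 5 (0.0929) and epithelial and amnion markers in 2 and 3 of 6 (0.839).

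In all, 13 of 34 lists were called with the preset correlation, 7 upward and 6 downward, and 1 with an estimated correlation; for 9 lists, 0 of them called, the median, mean and direction of the test differed in sign. Counts adjusted over the list alone were interferon 23 up and 2 down, proliferation 28 down, cholesterol 15 up, unfolded protein response 13 down, p53 targets 13 up, tip cell genes 10 down and mural ligands 3 up. They also differed for coagulation (11 up), proteases (7 down), endothelial identity (12 down), ATF4 (11 down), mesenchymal (12 down), BMP (7 up), senescence (9 down), smooth muscle (3 up) and leukocyte lists (3 up), and for 0 other lists. Without the libraries numbered 4, the antigen presentation (adjusted p = 0.0879) and ribosomal protein (adjusted p = 0.255) calls were lost, and with the replicate number as a block the arterial and Notch (0.0546), antigen presentation (0.0537) and YAP and TAZ (0.0537) calls were lost. The medians of the arterial, antigen presentation and YAP lists were -0.195, 0.056 and -0.069 with the block, the same as without it. This follows by construction, because each number occurs in each group, and says nothing about stability. With median-of-ratios rescaling the split of called genes was 2245 up and 2150 down, 51.1% up against 39.6% as deposited, and the count changed by at least 2-fold was 177 with a pseudocount of 0.1 and 65 with a minimum mean of 5 TPM, against 99.

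The changes in both transduced groups relative to NT were then set side by side. IGFBP5, STC1, SCUBE1, ADAMTS1 and GDF3 rose in both, and CXCR4, EDN1, BMP4, PDGFB, C10orf10 and CCL14 fell in both, each by more in TIE2-L914F. EDN1, for example, stood at 272 ± 12.7 TPM in NT, 136 ± 10.1 TPM in TIE2-WT and 7.14 ± 1.09 TPM in TIE2-L914F (SD, n = 4), and GDF3 at 5.91 ± 0.445, 13.6 ± 0.527 and 83.8 ± 2.98 TPM. Of the tested genes, 1168 rose in both groups, where independent lists would share 432, and 1753 fell in both, where 996 would be expected. Opposite changes were called for 497 genes. Of these, 288 rose in TIE2-L914F and fell in TIE2-WT, where independent lists would share 657. The other 209 rose in TIE2-WT and fell in TIE2-L914F, where 655 would be expected. FBLN5 and ACP5 were among the latter, FBLN5 with means below 1 TPM in NT (0.479) and TIE2-L914F (0.0846). Of the 2921 genes called in the same direction, 1574 were also called between TIE2-L914F and TIE2-WT and lay farther from NT in TIE2-L914F, 171 lay farther in TIE2-WT and 1176 were not called between them.

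Across genes, which are not independent replicates, the log2 changes correlated with r = 0.63. Unchanged groups simulated against the same NT libraries gave a mean of 0.496 and at most 0.607, so r alone lies close to the value that shared controls give. The covariance was 0.0841, against a mean of 0.00488 and at most 0.00777 in the 100 simulations, a difference of 0.0792. With the NT libraries split between the comparisons, r was between 0.551 and 0.592 over the 6 splits, and 867 to 903 genes rose and 1175 to 1272 fell in both.

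**Figure D4:**
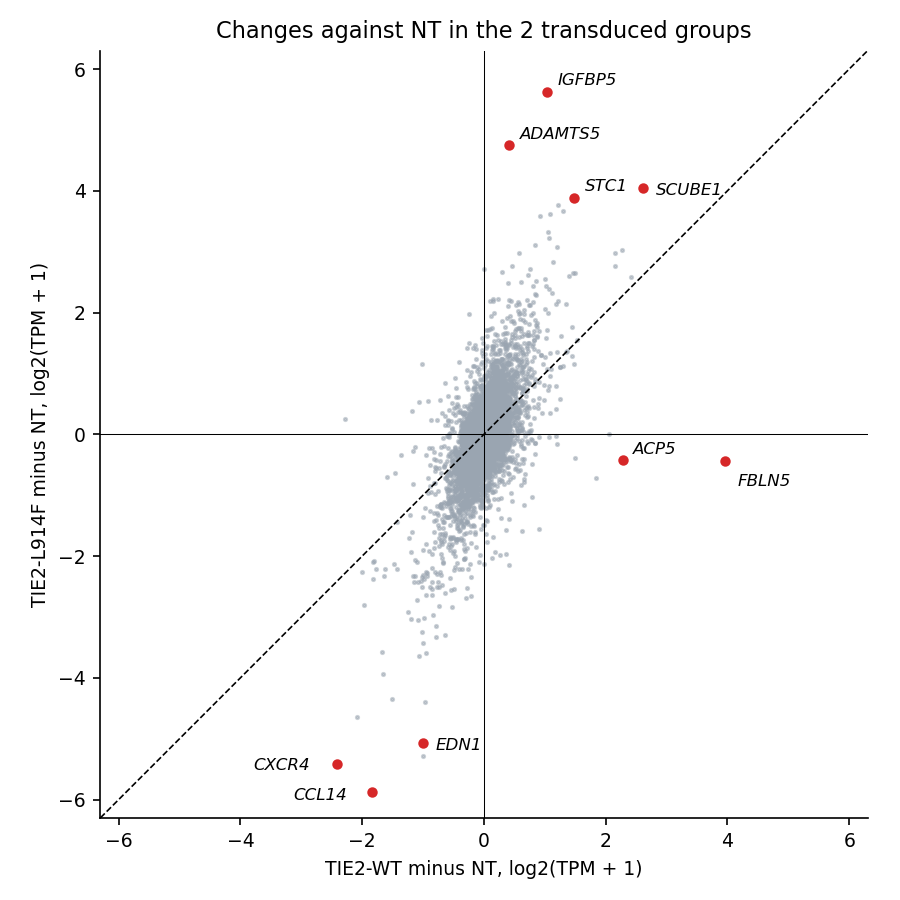
Log2(TPM + 1) change from NT in TIE2-L914F (vertical) against TIE2-WT (horizontal) for each tested gene except TEK, with 9 genes named; the dashed line marks equal changes. IGFBP5 (5.63 against 1.04) and EDN1 (-5.08 against -0.998) lay farther from NT in TIE2-L914F, and FBLN5 (-0.44 against 3.96) in TIE2-WT.

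Genes that differed in TIE2-L914F from both other groups in the same direction form the last comparison. IGFBP5, ADAMTS5, STC1 and ADAMTS1 were higher there than in either other group, and CXCR4, EDN1, BMP4 and CCL14 were lower. In all, 2262 genes were higher and 2981 lower in TIE2-L914F than in both, and 157 and 193 of these by at least 2-fold. Independent lists would share 754 and 1361 genes, but these comparisons share the TIE2-L914F libraries and are not independent. Unchanged groups simulated with shared TIE2-L914F libraries gave at most 0. Such groups give few calls by construction, so that count does not show how much the shared libraries add. With the TIE2-L914F libraries split between the comparisons, 1883 to 1941 genes were higher and 2268 to 2462 lower. TIE2-WT lay above both other groups for 578 genes and below both for 856, by at least 2-fold for 7 and 3 of them.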

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

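Of the tests in this part, those on ribosomal RNA and on the libraries numbered 4 followed a pattern noticed in the data, and the scaling of the library counts was chosen only after the result was seen. Single libraries of named genes stood apart from the other 3 of their group in 20 of 312 groups tested, by Dixon's criterion. Chance alone marks about 1 in 20 groups. FABP3 was listed at 0 TPM in NT 3, against 0.553 to 0.667 in the other NT libraries, and at 0.651 in TIE2-WT 1 against 1.27 to 1.37. In TIE2-WT 1, EDN1 was at 151 TPM (others 129 to 132), IER3 at 145 (137 to 138) and PGF at 214 (225 to 226). In TIE2-WT 2, YPEL3 was at 53.3 TPM (47.8 to 48.5) and FAP at 21.5 (23.4 to 23.7). LAPTM5 was at 112 TPM in TIE2-WT 3 (105 to 106) and the pseudogene A2MP1 at 2.36 in TIE2-WT 4 (3.40 to 3.57). Among NT libraries, ANGPT2 was at 57.7 TPM in NT 1 (49.4 to 50.4), RPL13A at 3610 in NT 2 (3480 to 3500), HLA-C at 214 in NT 3 (223 to 225), HYOU1 at 169 in NT 3 (others at 163) and CYR61 at 504 in NT 4 (482 to 485). CYR61 was at 47.4 TPM in TIE2-L914F 1 (55.5 to 57.1), PKM at 1730 in TIE2-L914F 2 (1800 to 1810) and MCM5 at 57.5 in TIE2-L914F 2 (61.1 to 61.4). In TIE2-L914F 4, YPEL3 was at 22.6 TPM (21.0 to 21.1), LYVE1 at 90.7 (93.4 to 93.6) and ME1 at 63.0 (66.4 to 67.1).

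The transduced groups moved in opposite directions from NT for 13 named genes and 2 lists, and the difference between the groups passed its test in each, for the lists only with the preset correlation. FBLN5 changed by 3.96 in TIE2-WT and by -0.44 in TIE2-L914F, a difference of -4.40. ACP5 changed by 2.28 and -0.43, a difference of -2.71. In the same order, BGN changed by 0.13 and -2.04 (difference -2.16), RPL5 by 0.08 and -0.15 (-0.23), RPL23 by 0.14 and -0.09 (-0.23) and RPS18 by 0.11 and -0.06 (-0.17). EBP changed by -0.12 and 0.79 (0.91), PDIA4 by -0.13 and 0.42 (0.55) and HYOU1 by -0.34 and 0.09 (0.43). Of the oxidative phosphorylation genes, ATP5G3 changed by -0.21 and 0.19 (0.40), ATP5G1 by -0.17 and 0.20 (0.37), CYC1 by -0.07 and 0.24 (0.31) and ATP5B by -0.07 and 0.16 (0.225). With median-of-ratios rescaling 8 of the 13 kept called changes in opposite directions; EBP, CYC1 and ATP5B no longer passed in TIE2-WT, nor RPL23 and RPS18 in TIE2-L914F (RPS18 at 0.00). With TEK left out of the total, 11 kept them. Unfolded protein response genes had a median of -0.08 in TIE2-WT and 0.18 in TIE2-L914F, and of 0.32 between the groups (adjusted p = 0.0811 with an estimated correlation). Ribosomal protein genes had medians of 0.02 and -0.09, and of -0.10 between the groups (adjusted p = 0.236 with an estimated correlation); their call in TIE2-L914F against NT was lost on rescaling (adjusted p = 0.201) and that in TIE2-WT against NT without the libraries numbered 4 (adjusted p = 0.255).

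The libraries numbered 4 stood apart in the same way in each group, with more ribosomal RNA and less of the nuclear RNA NEAT1, whose group means were 63.7 ± 18.1, 134 ± 37.5 and 61.5 ± 16.5 TPM in NT, TIE2-WT and TIE2-L914F (SD, n = 4). More ribosomal RNA in the TPM total is not the whole cause, because with it left out NEAT1 in number 4 was at most 0.725 of the lowest other library. Chance agreement between groups cannot be told apart from a shared preparation: 103 genes were highest in number 4 in all 3 groups as deposited, against up to 376 for another number, but 437 against up to 168 after rescaling. Lowest in number 4 in all 3 groups were 648 genes, against up to 164 for another number, and 358 against up to 284 after rescaling; number 4 thus led each count but the highest values as deposited, yet genes within a library move together, so the 190 expected of independent genes is no bound. No biological explanation was tested, since the labels give none for the numbers.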

How the results depend on the processing

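The alternatives without ribosomal RNA and without the libraries numbered 4 were chosen only after the data were seen. Each of the 166 results for genes in the comparison that named them kept its direction and its side of the threshold under every alternative that tested it, with 158 tested at a minimum mean of 5 TPM and 163 with TEK left out of the total. These genes were picked for large changes or small adjusted p, so their stability does not stand for all calls. With median-of-ratios rescaling, 6480 of 6822 calls were kept in TIE2-L914F against TIE2-WT, 6538 of 7415 in TIE2-L914F against NT and 3932 of 4497 in TIE2-WT against NT. Without the libraries numbered 4, 6008, 6677 and 3404 of these calls were kept. Counts of changed genes moved with an added 2-fold threshold, which by construction keeps fewer genes: to 400, 688 and 99 for TIE2-L914F against TIE2-WT, TIE2-L914F against NT and TIE2-WT against NT, and to 350 for TIE2-L914F against both. The 2-fold counts were 601 (TIE2-L914F against TIE2-WT) and 177 (TIE2-WT against NT) with a pseudocount of 0.1, which gives low genes larger changes, and 261 and 65 with a minimum mean of 5 TPM, which tests fewer genes. Under the other alternatives each count stayed within 1.5 times its value. With each library left out in turn, the counts were 6319 to 6845, 6963 to 7499, 3931 to 4617 and 4906 to 5246 in the same order, and without the libraries numbered 4 they were 6296, 6926, 3586 and 4873.

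With an estimated correlation, 3, 6 and 1 lists were called in place of 23, 21 and 13; the estimate rests on 12 libraries. Rescaling ended the call of ribosomal proteins in TIE2-L914F against NT (adjusted p = 0.201), and leaving out the libraries numbered 4 ended 3 calls; the cause was not tested. With the NT libraries split, the correlation between changes relative to NT was 0.56, 0.563, 0.571, 0.551 and 0.569 in 5 splits and 0.592 in the other, against 0.63; by construction the split removes the shared libraries and leaves fewer per group.

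The labels do not say whether the numbers pair the samples, and the tables leave it open for number 4: of 12 pairs with the same number, 2, both of number 4, had a correlation of deviations over 0.1 (range -0.076 to 0.236), and 4 of 12 libraries correlated best with their own number. With a replicate block the counts were 6913, 7509, 4538 and 5322, and 3 list calls in TIE2-WT against NT ended: arterial and Notch (adjusted p = 0.0546), antigen presentation (0.0537) and YAP and TAZ genes (0.0537). The depth of the libraries is unknown, so how far it limits genes with low TPM cannot be stated.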

Other observations

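The gene families described here were chosen after their values were seen, as were the tests of the TEK amount, of leukocytes and of the introduction of a construct; the splits of the libraries and the test of shared NT libraries were set beforehand. Some of their members also stand in the fixed lists (6 of 16 BMP and related genes, 2 of 13 semaphorins, SEMA3A among them, and 2 of 5 IGFBP genes), so their counts partly repeat those of the lists. Among 16 BMP, GDF, activin, TGF-beta and follistatin genes tested, 6 rose and 9 fell between TIE2-L914F and TIE2-WT, and 2 rose and 12 fell between TIE2-WT and NT. The activin subunit gene INHBA was at 25.1 ± 1.48 TPM in NT, 13.5 ± 0.317 in TIE2-WT and 3.18 ± 0.189 in TIE2-L914F (SD, n = 4), and its antagonist gene FST at 48.3 ± 2.24, 14.6 ± 1.33 and 2.24 ± 0.370 TPM. TGFB3 went the other way, at 3.19 ± 0.544, 3.44 ± 0.178 and 12.7 ± 0.435 TPM. The axon guidance and vascular repulsion genes SEMA3A and SEMA3F rose between TIE2-L914F and TIE2-WT by 2.04 and 1.05 on the log2 scale, among 5 of 13 semaphorin genes that rose and 5 that fell. SEMA3A stood at 11.5 ± 0.886, 12.7 ± 0.196 and 55.7 ± 2.28 TPM in NT, TIE2-WT and TIE2-L914F.

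Of 3 HLA class II genes tested, 3 rose in each transduced group relative to NT. HLA-DMA was at 0.616 ± 0.293, 1.62 ± 0.431 and 1.96 ± 0.485 TPM in NT, TIE2-WT and TIE2-L914F, and HLA-DPB1 at 0.615 ± 0.0422, 1.02 ± 0.151 and 4.09 ± 0.671 TPM. Both had NT means below the filter of 1 TPM and passed it only through the transduced groups, which favours rises. HLA-DMA did not pass the threshold between TIE2-L914F and TIE2-WT (limma adjusted p = 0.346). HLA-DPA1 was at 2.05 ± 0.407 TPM in NT, 4.39 ± 0.0461 in TIE2-WT and 14 ± 0.737 in TIE2-L914F. Lipid transporter genes of the ABCA family fell in 6 of 8 cases and rose in 1 between TIE2-L914F and TIE2-WT. ABCA6 was at 9.86 ± 0.910, 4.47 ± 0.575 and 0.344 ± 0.0291 TPM, and ABCA9 changed by -1.52 on the log2 scale. IGFBP2 rose beside IGFBP5, from 30.1 ± 1.95 TPM in TIE2-WT to 67.8 ± 3.39 in TIE2-L914F, while the other 3 of 5 binding protein genes tested fell.

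Genes that differed in TIE2-WT from both other groups by at least 2-fold were few, and they are named here after their values were seen. FBLN5, ACP5, PPL (2.78 ± 0.0950 TPM in TIE2-WT, 0.347 ± 0.0356 in NT), CRTAC1, NEAT1, SNORD3A and A2MP1 were higher, and PMCH, RASAL3 and NSFP1 were lower. SNORD3A (11.7 ± 8.86 TPM in TIE2-WT, 3.77 ± 4.22 in NT) and NEAT1 (134 ± 37.5 and 63.7 ± 18.1 TPM) varied widely between libraries, and A2MP1 and NSFP1 are pseudogenes, so their values are uncertain.

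Other divisions of the libraries did not give the counts of changed genes: 1 of the 35 splits of the 8 libraries, the real one, gave as many as 6822, 7415 and 4497 genes for TIE2-L914F against TIE2-WT, TIE2-L914F against NT and TIE2-WT against NT, with at most 2, 1 and 1 in another split. For TIE2-L914F against both other groups, 1 of 100 groupings of the 12 libraries, the real one, reached 5243 genes, with at most 0 in another. Mixed splits add the difference between such distinct groups to the spread, so few calls there follow largely by construction. The splits show that the counts follow the group labels. They cannot tell the receptor from a culture or preparation that differed between the groups. Lists were called less distinctly, with 23, 21 and 13 in the real split, which was again 1 of 35, and up to 19, 17 and 10 in another. Among the 18 splits that mix the groups evenly, the highest were 3, 3 and 4, so the higher counts came from splits that kept 3 of 4 libraries of a group together.

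The mean log2(TPM + 1) of the interferon response list was 3.92 ± 0.028 in NT, 4.22 ± 0.065 in TIE2-WT and 5.29 ± 0.032 in TIE2-L914F. More TEK transcript giving a higher list mean would run the other way, since TIE2-L914F held less TEK (-0.50) and had the list mean higher by 1.075. The exact permutation p for that difference was 0.0286 over 70 splits, two-sided, the smallest they can give. It concerns only a difference between groups that the list test had already called, and does not test the TEK amount. Leukocytes in the TIE2-L914F cultures are argued against by 10 of the 20 leukocyte transcripts listed, chosen after their values were seen as abundant in such cells, of which the highest, CD79A, reached 0.146 TPM and PTPRC was at 0; of the 10 set aside, LAPTM5 (235 TPM), CD68 (61.5), CD14 (4.29), CORO1A (3.20) and FCER1G (1.49) were above 1 TPM. An effect of construct introduction alike in both groups leaves a gap of 0.952 between the lowest TIE2-L914F and the highest TIE2-WT library unexplained. A different response to the mutant receptor is a candidate explanation and may account for the gap, but a difference in preparation between the transduced groups was not tested.

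Called changes relative to NT ran in the same direction in both transduced groups more often than independent lists would give. Over all tested genes, 67.6% had the same sign, and unchanged groups simulated with shared NT libraries gave a mean of 66.7%. That simulation holds no changed genes, so the likeness of the shares does not measure what the shared libraries add here. The covariance was 0.0841, against a mean of 0.00488 in the simulations. Noise of single NT libraries is not the whole cause, as the correlation stayed at 0.551 or above with the NT libraries split. A culture or preparation that set all NT libraries apart would remain in each part of a split, so the splits cannot exclude it. If changes scaled with TEK transcript alike for both receptors, the slope of the TIE2-L914F changes on the TIE2-WT changes would be at most 1. It was at least 1.066 over the splits. That scaling was assumed and not measured, so the slope does not decide on the TEK amount. Of those same-direction genes that also differed between the groups, 90.2% lay farther from NT in TIE2-L914F (1574 against 171). Introduction of a construct, alike in both groups, does not give these differences in size. The share cannot decide whether it underlies the common direction, because genes that changed alike were left out by selection. For the 1176 genes not called between the transduced groups, construct introduction and receptor activity cannot be told apart, because no group received a construct without TIE2.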
